A study of Micropterus salmoides with 6 samples.

How the data were processed

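The libraries were made from the intestine of largemouth bass (Micropterus salmoides), a warm-water fish kept at 26 °C and, for the heat group, at 34 °C. Both groups were sampled after 9 h, per the labels. Per the labels' protocols, 120 fish weighing 25.2 ± 3.6 g were acclimated for 2 weeks and then divided at random between both temperatures, with 3 parallels each. Each library pooled equal amounts of intestine from 3 fish of 1 parallel, so n = 3 pools per temperature and the spread between pools understates the spread between single fish. Total RNA was extracted with Trizol and made into libraries with a total RNA kit, per the labels' protocols. Neither the strand setting of the counting nor the clock time of sampling is given in the sources used here.

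The authors deposited a whole-number count and a TPM value (length-scaled transcript abundance) for each feature and library in both a gene table and a lncRNA table, per the file headers. The submitters' processing notes name HISAT2 2.1.0, StringTie 1.3.3 and DESeq, without a role for each. The genome build is not given in the sources used here. Gene positions below are those of the deposited tables, which use NCBI scaffold names. A reference gene table of assembly ASM1485139v1 was used for gene biotypes only, and 33187 of the 35854 gene identifiers matched it. The gene table also holds 2488 assembled genes whose counts equal the summed counts of the 3399 lncRNA transcripts in every library. These genes were taken out of the gene class so that each read was used once, at the transcript level.

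Total counts of the gene table were 28.8 M, 13.9 M and 12.3 M in control replicates 1, 2 and 3, and 8.24 M, 15.7 M and 14.4 M in heat replicates 1, 2 and 3. Counts as deposited were tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, after filterByExpr with a minimum count of 10 and a minimum total of 15 and with TMM scaling. Genes and lncRNA transcripts entered 1 joint fit without a replicate term, and p was adjusted by the Benjamini-Hochberg method within each class, with a threshold of 0.05 and no fold minimum. The filter left 20326 genes and 1734 lncRNA transcripts. A log2 fold change is heat minus control, and its standard error (SE) was taken from the F statistic. CPM (counts per 1e+06 on TMM-scaled library sizes) are given as mean ± SD over n = 3. The common biological coefficient of variation was 0.436.

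On data simulated for this comparison with 20326 genes, 0% of the 50 genes changed 2-fold were recovered, 34% at 4-fold, 64% at 8-fold and 92% at 16-fold. Of the 98 calls, 3.06% fell on unchanged genes and 0 had the wrong sign. A list of 30 genes raised 2-fold was called, and 0 of 20 random lists were. The simulated genes were drawn independently and without an outlying library. The list result therefore does not show how the list test behaves with correlated genes. Folds between 2 and 4 were not simulated.

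The 33 gene lists were fixed before the data were examined, by symbol and, for genes with a locus number, by product description. They were tested on log2 CPM (prior count 2) with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The list of cytoplasmic ribosomal proteins took in 7 genes of S6 kinases through its symbol pattern. KEGG and GO terms of the gene table with 10 to 500 tested genes were tested the same way. Genes named in the text follow a rule fixed at the same time. Its first part takes, per direction, the 8 largest changes among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and an informative name. Its second part takes up to 3 members per list with the smallest adjusted p past the threshold. Its next part takes a set of chaperone, cytokine and barrier genes whatever their p, with at most 2 copies each. The last part, for lncRNAs past the threshold, took none. For that set, hsph1 matched no identifier, and no copy of tnf or cxcl8 passed the count filter.

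Alternatives fixed beforehand were DESeq2 1.42.0, RLE and upper-quartile scaling, no count filter, a minimum absolute log2 fold change of 1, each library left out, a replicate block, the lncRNA table alone, and for the lists other correlations, tests and membership. A limma fit on FPKM was planned, but the tables hold TPM, so log2(TPM + 1) with a mean TPM of at least 0.5, log2(TPM + 0.1) and no filter were used. These, robust dispersion, voom with sample quality weights, genes fitted without lncRNA transcripts and lncRNAs summed per assembled gene were chosen after seeing the data. Near-identical copies, such as those of HSP70, and genes that overlap another gene may share reads, and their separate values are uncertain.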

Results

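Intestinal RNA was measured in 6 libraries of largemouth bass, 3 from fish held at 26 °C and 3 from fish held at 34 °C, both sampled after 9 h. Each library was a pool of 3 fish from 1 parallel of the rearing design. Total counts ranged from 8.24 M in heat replicate 1 to 28.8 M in control replicate 1. Control replicate 1 stood apart from the other controls: across genes and lncRNAs its log2 CPM correlated with theirs at 0.875 and 0.853, while they correlated with each other at 0.932. Mitochondrial features held 2.14% of its counts, against 7.08% and 9.05% in the other controls and 5.24% to 7.64% in the heat libraries. Heat replicate 1 also differed, with 5.69% of counts in annotated rRNA against 0.134% to 1.43% in the other libraries. The lncRNA table held 17.5% of its counts against 3.39% to 9.68%, and protein-coding genes 75.4% against 88.3% to 95.8%. Part of that lncRNA share was MSTRG.9, an assembled gene of the mitochondrial 12S region (3.92% against 0.169% to 3.00%). The assembled gene MSTRG.25006 held a further 7.72% against 1.42% to 3.31%. The lncRNA class thus also holds structural RNA. In control replicate 1 the cytoplasmic ribosomal protein list lay 1.96 and the respiratory chain list 2.03 log2 units above the other controls (list medians), against 0.09 for the median of all genes.

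The comparison asked which genes and lncRNAs differ in the intestine after acute heat. At 34 °C, 120 genes were higher and 80 lower of 20326 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). They included lower clock repressors, higher inducible HSP90 and HSP70 genes, higher glucocorticoid-responsive genes and lower smooth muscle genes. Absolute log2 fold changes of the 200 genes ran from 1.3 to 8.45, with a median of 2.53, and 197 were annotated as protein coding. The median over all tested genes was -0.12. The count depended on single libraries: it was 1825 without control replicate 1, 0 without control replicate 2, 10 without control replicate 3, and 1, 0 and 0 without heat replicates 1, 2 and 3. All 200 genes kept their direction in each of these fits. That is no test, since control and heat libraries did not overlap for any of the 200. Each other split of the libraries into 3 and 3 gave more camera lists, 10 to 15 against 7 for temperature. The list results below therefore do not by themselves set the temperature groups apart.

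Genes of the circadian clock split, with more members lower than higher. Of 28 tested members, 8 fell, 1 rose and 19 did not pass, and 17 had a log2 fold change below 0 and 11 above (median -0.63). The list's camera adjusted p was 0.00229, and its adjusted p = 0.934 with an estimated correlation. Adjusted over the list alone, 11 fell and 4 rose. The period gene per1b (NW_024041150.1, 27287068 to 27304560), a repressor of the clock, was at 211 ± 40.4 CPM in the controls and 14.2 ± 0.856 CPM in the heat group, 14.9-fold lower (log2 fold change -3.89, SE 0.29, edgeR adjusted p = 0.00811). The related per3 (NW_024043372.1, 25904673 to 25925108) was 15.4-fold lower, at 256 ± 56.7 against 16.5 ± 7.96 CPM (edgeR adjusted p = 0.0228). The gene nr1d1 (NW_024040041.1, 35031942 to 35041612), which encodes the nuclear receptor REV-ERB alpha, was 21.9-fold lower (log2 fold change -4.45, SE 0.50). Both circadian-associated repressor genes were lower too, ciarta from 20.2 ± 2.22 to 0.424 ± 0.635 CPM and its relative LOC119897558, which the list does not hold, from 10.8 ± 1.96 to 0.511 ± 0.353 CPM. The bZIP repressor nfil3-5 (NW_024040263.1, 25897099 to 25906871), which is outside the list, rose 31.0-fold from 1.91 ± 0.351 to 59.11 ± 15.4 CPM (edgeR adjusted p = 0.00811).

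**Figure D1:**
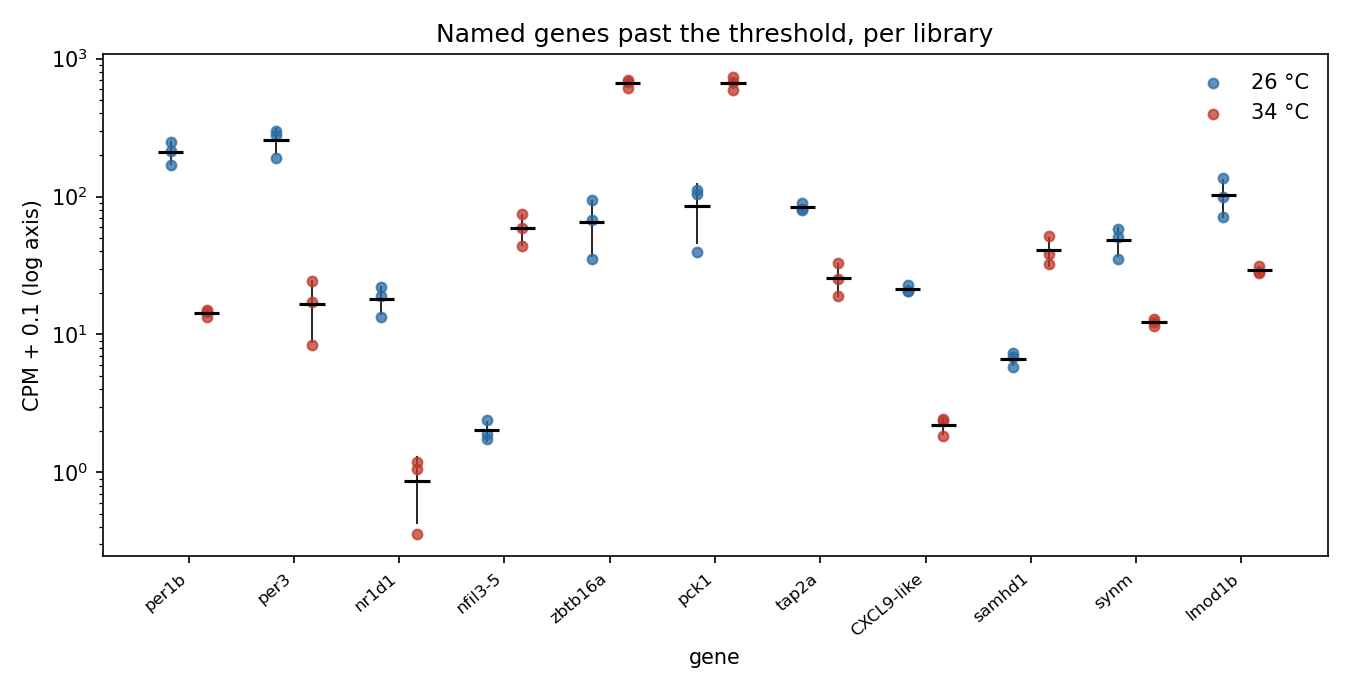
CPM + 0.1 on a log axis of 11 named genes past the threshold, with 1 dot per library (blue 26 °C, red 34 °C, 3 each), the mean as a horizontal bar and 1 SD as a vertical line. The 3 heat libraries lie on 1 side of the 3 control libraries for each gene, and per1b falls from 211 to 14.2 CPM.

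Heat shock proteins and co-chaperones passed as a higher list, with 4 members higher, 2 lower and 55 not past the test of 61, and a median log2 fold change of 0.36 (camera adjusted p = 1.8e-05, adjusted p = 0.934 with an estimated correlation). Control replicate 1 lay at the level of the heat libraries, with a list median of 0.24 against 0.20 to 0.45, while the other controls lay at -0.53 and -0.74. Adjusted over the list alone, 12 rose and 3 fell. The inducible cytosolic chaperone hsp90aa1.2 (NW_024040928.1, 10859769 to 10865573) rose 25.4-fold, from 3.33 ± 1.86 to 86.0 ± 20.1 CPM (log2 fold change 4.67, SE 0.47, edgeR adjusted p = 0.0203). Its tandem neighbour hsp90aa1.1 was at 1.74 ± 0.393 and 3.52 ± 1.02 CPM and did not pass (edgeR adjusted p = 0.292). The HSP70 copies LOC119895311 and LOC119895319 (NW_024040041.1, 32965695 to 32968307 and 32962209 to 32964732) were 18.3-fold and 16.7-fold higher, from 0.473 ± 0.248 and 0.500 ± 0.256 CPM to 8.58 ± 3.70 and 8.27 ± 3.49 CPM; these neighbouring copies may share reads. The other members past the threshold, chosen after their values were seen, were the HSP70 copy LOC119895269 (log2 fold change 4.33, SE 0.76), which was higher, and the co-chaperone gene dnajb5 (-2.69, SE 0.42) and the small heat shock protein gene hspb9 (-4.60, SE 0.80), which were lower. A further copy, LOC119896543, was at 0.756 ± 0.568 and 10.9 ± 3.52 CPM (edgeR adjusted p = 0.0525). The list's median was 0.90 and its adjusted p 4.5e-08 without control replicate 1, where 24 members were higher and 2 lower. That was its smallest camera adjusted p with 1 library left out, and the largest was 0.0003855.

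Several chaperone genes named beforehand did not pass with all 6 libraries. The cognate chaperone LOC119895682 (HSC71) was at 1649 ± 1608 and 2031 ± 386 CPM (edgeR adjusted p = 0.861), and hsp90ab1 at 1533 ± 1023 and 2587 ± 315 CPM (edgeR adjusted p = 0.521). The second HSC71 copy, LOC119895688, was at 218 ± 146 and 400 ± 86.2 CPM. The mitochondrial chaperone hspd1 was at 51.2 ± 45.3 and 192 ± 68.2 CPM (log2 fold change 1.90, and 2.81 with edgeR adjusted p = 0.0629 without control replicate 1), and hspa5 of the endoplasmic reticulum at 53.9 ± 34.4 and 156 ± 29.1 CPM. Without control replicate 1, the log2 fold changes of LOC119895682, LOC119895688, hsp90ab1 and hspa5 were 1.505, 1.60, 1.46 and 2.13 with edgeR adjusted p of 0.0226, 0.0177, 0.0207 and 0.0272. These were the highest values with 1 library left out, and the lowest were -0.09, 0.63, 0.45 and 1.18. For hspd1 the lowest was 1.435. The fit without control replicate 1 was singled out after that library was seen to differ, and it called 1825 genes against 200. The collagen chaperone genes serpinh1b and serpinh1a had log2 fold changes of 0.95 (SE 0.34) and -0.62 (SE 0.52) and did not pass. The heat shock factor hsf1 was at 70.2 ± 38.6 and 67.6 ± 6.38 CPM, and the cold-inducible RNA-binding protein gene cirbpb at 433 ± 113 and 167 ± 5.20 CPM (edgeR adjusted p = 0.0815 in all libraries, 0.0151 without control replicate 1).

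**Figure D2:**
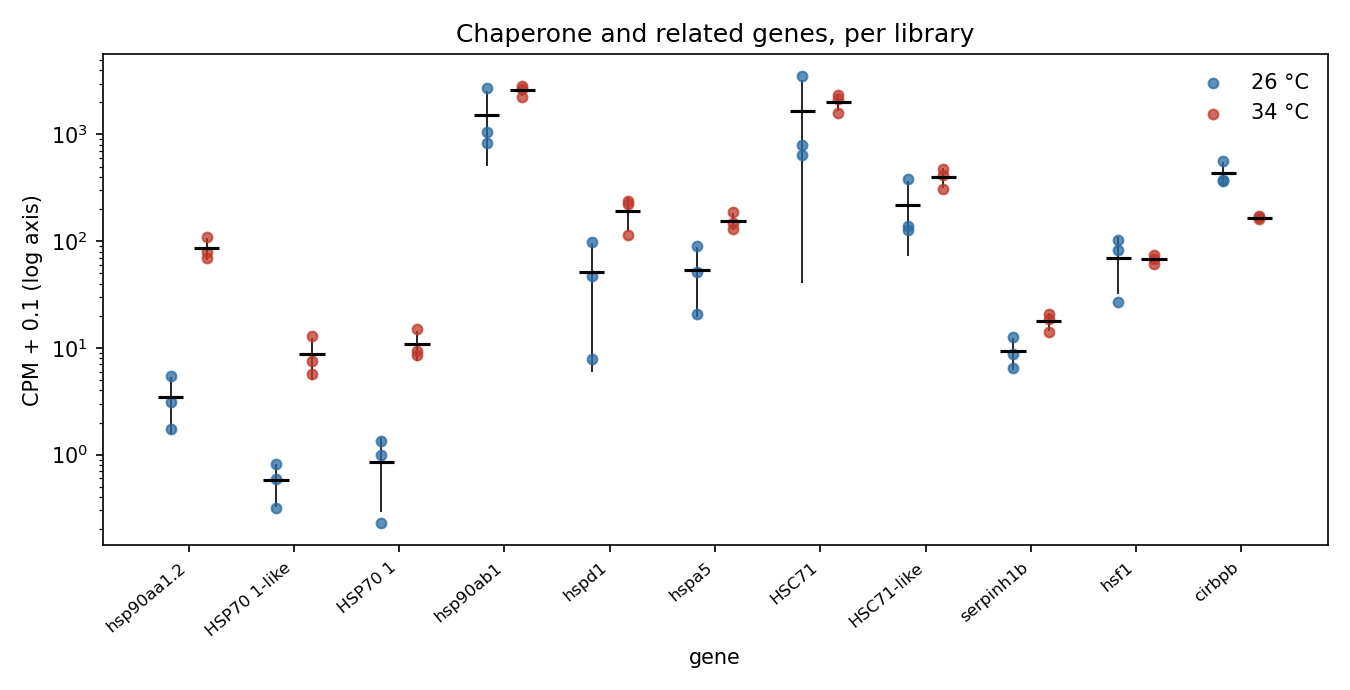
CPM + 0.1 on a log axis of 11 chaperone and related genes, with 1 dot per library (blue 26 °C, red 34 °C, 3 each), the mean as a horizontal bar and 1 SD as a vertical line. The inducible hsp90aa1.2 separates by group, 3.33 against 86.0 CPM, while the HSC71 controls spread widely around 1649 CPM.

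The unfolded protein response of the endoplasmic reticulum, a list of 47 genes, passed as higher, with 1 member higher and 46 not past the test (median log2 fold change 0.31, camera adjusted p = 0.000762, adjusted p = 0.934 with an estimated correlation). Of its members 28 had a log2 fold change above 0 and 19 below, and control replicate 1 lay above each heat library, with a list median of 0.48 against 0.04 to 0.38. Adjusted over the list alone, 2 rose. The member past the threshold was chac1, an enzyme that degrades glutathione, from 20.6 ± 4.797 to 81.0 ± 27.8 CPM (3.92-fold). Without control replicate 1, 17 members were higher and the median was 0.89. The list's camera adjusted p was smallest in that fit (5.3e-08) and at most 0.0337 with 1 library left out.

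Glucocorticoid-responsive genes rose as a list (camera adjusted p = 0.00379, 0.934 with an estimated correlation), with 3 of 18 members higher, 1 lower, 14 not past the test and a median log2 fold change of 1.02. Adjusted over the list alone, 9 rose and 3 fell. The zinc finger gene zbtb16a (NW_024044681.1, 13343667 to 13481663) rose 10.1-fold, from 65.4 ± 29.4 to 664 ± 48.0 CPM (log2 fold change 3.34, SE 0.43, edgeR adjusted p = 0.0259). The gluconeogenic enzyme gene pck1 (NW_024043372.1, 8070750 to 8076409) rose 7.87-fold, from 84.9 ± 39.6 to 669 ± 68.7 CPM (edgeR adjusted p = 0.0358). The member that fell was per1b, which the clock list also holds. Clock times of sampling are not given, so a difference in them between the groups could bear on this list too, which was not tested.

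Smooth muscle markers fell, with 4 of 18 members lower and 14 not past the test (median log2 fold change -1.03, camera adjusted p = 2.4e-05, 0.934 with an estimated correlation). Adjusted over the list alone, 8 fell. The intermediate filament gene synm was 3.94-fold lower, at 48.0 ± 11.9 against 12.2 ± 0.693 CPM. The contractile-apparatus genes smtna and lmod1b were 4.29-fold and 3.51-fold lower (log2 fold changes -2.103, SE 0.30, and -1.81, SE 0.30). Of the other muscle list, skeletal muscle markers, 0 of 7 tested genes passed in edgeR (3 at an unadjusted p under 0.05; camera adjusted p = 0.423). Its median log2 fold change was -0.96, and -1.12 without control replicate 1, where 4 of 9 tested members were lower (camera adjusted p = 0.0949).

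The cell cycle and cholesterol synthesis lists also fell by camera (adjusted p = 0.000715 for both, 0.934 with an estimated correlation), although edgeR called 0 of 49 and 0 of 22 members. At an unadjusted p under 0.05 there were 15 and 10 members. Median log2 fold changes were -0.76 and -0.96, with 45 of 49 and 19 of 22 members below 0. For the cell cycle list control replicate 3, at a list median of -0.59, lay below the heat libraries (-0.03, -0.41 and -0.47), and the difference rested on control replicates 1 and 2 (0.68 and 0.86). Adjusted over the list alone, 1 cell cycle gene was higher and 3 cholesterol synthesis genes were lower. Without control replicate 1 the medians were -0.51 and -0.38, and the cell cycle list did not pass without control replicate 2 (camera adjusted p = 0.104).

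**Figure D3:**
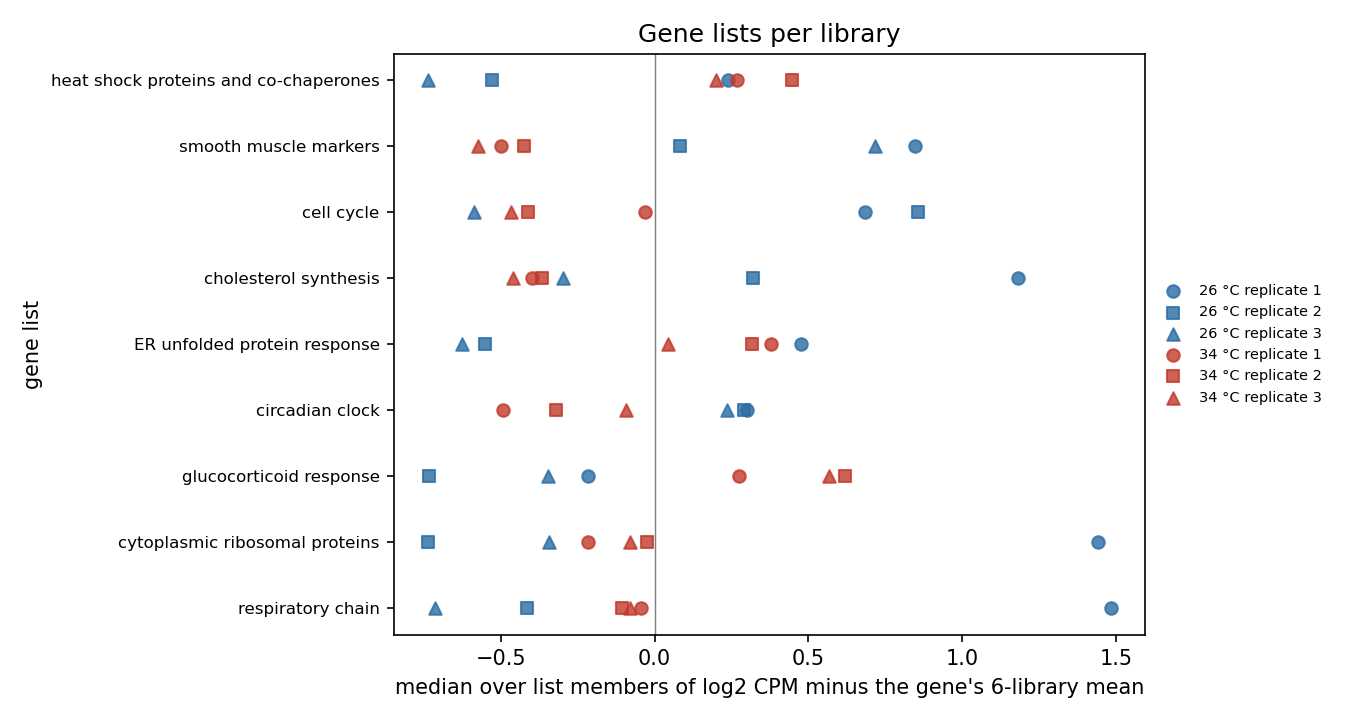
Median over list members of log2 CPM minus each gene's mean over the 6 libraries (x axis) for the 7 lists past the threshold and for ribosomal protein and respiratory chain genes, with 1 symbol per library (blue 26 °C, red 34 °C, shape for the replicate). Control replicate 1 lies at 1.44 for ribosomal proteins and 1.48 for the respiratory chain, apart from the other 5 libraries.

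Immune genes went both ways. Of 30 tested genes of MHC class I antigen presentation, 1 was lower (median log2 fold change -0.62, camera adjusted p = 0.0567, and 0.934 with an estimated correlation), the peptide transporter subunit tap2a (NW_024040817.1, 8603586 to 8610245), at 83.2 ± 4.97 against 25.6 ± 7.02 CPM (3.25-fold, edgeR adjusted p = 0.0379). The list's median was -0.18 without control replicate 1 (camera adjusted p = 0.576), and it passed as lower without control replicates 2 and 3 and heat replicate 1 (0.0326, 0.00252 and 0.00861) but not without heat replicates 2 and 3 (0.270 and 0.128). It also passed with upper quartiles, no filter and symbols alone (0.0412, 0.0325 and 0.00139). Among 46 inflammatory cytokine and NF-kB genes, 2 were higher and 1 lower. The CXCL9-like chemokine gene LOC119916870 (NW_024041373.1, 14006001 to 14007812) fell 10.2-fold, from 21.3 ± 1.27 to 2.103 ± 0.331 CPM (edgeR adjusted p = 0.0170); it overlaps rassf4a on the opposite strand. The CCL20 genes ccl20b and LOC119883985 were 12.04-fold and 12.2-fold higher, at 4.99 ± 1.67 and 4.798 ± 1.79 CPM in the heat group and 0.396 ± 0.181 and 0.374 ± 0.207 CPM in the controls, and may share reads. The interferon-linked samhd1 rose 6.22-fold, from 6.56 ± 0.792 to 40.9 ± 10.1 CPM (edgeR adjusted p = 0.0203), the only one of 32 interferon-stimulated genes past the threshold. That list ran the other way, with 22 members below 0 and a median log2 fold change of -0.49, and adjusted over the list alone 6 were lower and 2 higher. The gut-homing chemokine receptor ccr9a rose 4.52-fold and the transcription factor cebpb 7.49-fold, each the only member of its list (T cell markers, and macrophage and granulocyte markers) to pass. The medians of these lists were -0.59 and -0.33, with 19 of 27 and 18 of 28 members below 0, and adjusted over the list alone 1 T cell gene was higher and 1 lower, and 4 macrophage genes were higher. LOC119912128, described as complement C1q-like protein 2, entered the complement list through that description, and an immune role was not tested. Its level was 9.70 ± 5.44 CPM in the controls and 0.0824 ± 0.0715 CPM in the heat group. The cytokine il1b was at 4.20 ± 1.13 and 4.06 ± 0.556 CPM (edgeR adjusted p = 0.966).

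The barrier genes named beforehand did not pass, nor did the beta-2-microglobulin-like genes. The tight junction genes tjp1a and tjp1b had log2 fold changes of 0.17 (SE 0.26) and -0.17 (SE 0.34). The mucin-2-like genes LOC119898530 and LOC119893780 were at 3499 ± 3478 and 3026 ± 3226 CPM in the controls and 2638 ± 470 and 2080 ± 393 CPM in the heat group. Their signs turned without control replicate 1, to log2 fold changes of 0.83 and 0.85. The beta-2-microglobulin-like LOC119918458 and LOC119918460, which are members of the MHC class I list and not barrier genes, turned likewise, from -0.40 and -0.27 to 0.44 and 0.61.

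Further named genes covered proteases, transcription factors and metabolism. The ADAMTS9-like protease gene LOC119885549 rose 47.5-fold, from 1.51 ± 0.685 to 70.7 ± 2.76 CPM (edgeR adjusted p = 0.00811), and adamts1 rose 19.5-fold. The c-Fos-like genes LOC119908415 and LOC119909126 rose 31.3-fold and 14.9-fold. The telomerase gene tert rose 16.8-fold, from 4.57 ± 2.58 to 76.2 ± 17.9 CPM, and the obscurin-like LOC119901990 rose 21.1-fold. The log2 fold change of LOC119901990 was 4.40, and 4.099 to 5.101 with 1 library left out. The splicing factor gene srsf3a rose 5.78-fold, the lipid droplet gene plin2 4.76-fold and the growth factor gene vegfaa 3.21-fold. The natterin-3-like genes LOC119891880 and LOC119917804 fell 12.1-fold and 11.6-fold (edgeR adjusted p = 0.0451 and 0.0446). They were at 93.6 ± 62.5 and 85.2 ± 56.6 CPM in the controls, with control replicate 3 at 24.6 and 23.8 CPM. Their values were close in each library, and they may share reads. The neuralized-like LOC119892446 fell 20.1-fold, the trypsin-like LOC119918082 10.7-fold and the peptidase gene naalad2 6.39-fold. With 1 library left out, log2 fold changes ranged from -4.713 to -3.555 for LOC119892446 (-4.33 with all) and -3.36 to -2.38 for naalad2 (-2.67).

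Of the 33 lists 7 passed with camera, against 0 with an estimated correlation and 0 with fry. The count was 7 with RLE scaling and robust dispersion, 9 with upper quartiles, no filter, genes without lncRNA transcripts or quality weights, and 10 with symbols only. Without control replicates 1, 2 and 3 the count was 10, 14 and 18, and without heat replicates 1, 2 and 3 it was 11, 7 and 7. Each other split of the libraries into 3 and 3 gave 10 to 15 lists at the preset correlation, more than the temperature split. For the 7 lists, the shared adjusted p of 0.934 hides unlike values. Unadjusted camera p with an estimated correlation was 0.0562 for glucocorticoid response, 0.0965 for smooth muscle and 0.115 for heat shock proteins. It was 0.162 for the clock, 0.226 for cholesterol synthesis, 0.393 for the unfolded protein response and 0.415 for the cell cycle. The other lists did not pass with all libraries at the preset correlation. Camera adjusted p was 0.0567 for fatty acid oxidation (median log2 fold change -0.58) and 0.0822 for digestive tract hydrolases and chitin handling (-0.67). Without control replicates 2 and 3 and heat replicate 1 both passed as lower, at 0.00611, 0.00988 and 0.0348 for the first and 0.00549, 0.0216 and 0.0121 for the second. Without control replicate 1 and heat replicates 2 and 3 neither passed, at 0.818, 0.262 and 0.0965, and at 0.927, 0.247 and 0.248. Fatty acid oxidation also passed with upper quartiles, no filter, symbols only and genes without lncRNA transcripts (0.0412, 0.0344, 0.0495 and 0.0433), and the hydrolases with symbols only (0.0296). Camera adjusted p was 0.211 for interferon-stimulated genes, 0.228 for hypoxia and glycolysis, and 0.268 both for cytokines and for cold-inducible and splicing factors. It was 0.298 for early response transcription factors and for apoptosis and p53 targets, 0.407 for oxidative stress and 0.419 for the enterocyte brush border. It was 0.423 for ribosomal proteins, tight junctions, T cells, erythrocytes, the respiratory chain and liver markers, 0.459 for complement and 0.489 for the proteasome. It was 0.507 for MHC class II, 0.660 for pathogen sensing, 0.747 for B and plasma cells, 0.891 for goblet and enteroendocrine cells, and 0.958 for macrophages and granulocytes and for exocrine pancreas. Without control replicate 3, hypoxia and glycolysis passed as higher (camera adjusted p = 0.0337) and cytokines as lower (0.0473). Early response transcription factors passed as higher without heat replicate 1 (camera adjusted p = 0.0280).

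Among lncRNA transcripts, edgeR called 0 of 1734 (smallest adjusted p = 0.111), with 166 higher and 85 lower at an unadjusted p under 0.05. The whole class was shifted, with a median log2 fold change of 0.18 against -0.12 for genes. With lncRNAs summed per assembled gene, a fit chosen after seeing the data, edgeR called 0 lncRNAs and 283 genes. DESeq2 called 125, 86 higher and 39 lower. The edgeR count was 45 without control replicate 1 (13 higher, 32 lower), 2 without control replicate 2, 3 without heat replicate 2, and 0 without each of the other libraries. Between libraries of 1 group, lncRNA transcripts of 1 to 10 CPM had a median SD of 0.92 log2 units, against 0.54 for genes of that level. In the gene class, 3 of 631 genes annotated as lncRNA passed, and they were higher in the heat group: LOC119904203 (4.45 ± 0.817 CPM), LOC119901458 (9.16 ± 3.77 CPM) and LOC119889754 (2.45 ± 0.897 CPM), against 0.0692 ± 0.0854, 0.153 ± 0.166 and 0.0274 ± 0.0475 CPM in the controls. They were chosen after their values were seen. Of 514 KEGG and GO terms, 0 passed with camera (56 at an unadjusted p under 0.05; 0 with an estimated correlation). Without control replicates 1, 2 and 3 the count of terms was 28, 8 and 3, and without heat replicates 1, 2 and 3 it was 2, 0 and 0.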

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

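Tests chosen only after the result was seen are the TPM fits, robust dispersion, voom with quality weights, the fit of genes without lncRNA transcripts and the sums per assembled gene; the cause of a change below was not tested unless stated. Leaving out a library leaves fewer samples. DESeq2 called 1437 genes (688 higher, 749 lower) and 125 lncRNAs, and its genes included the 200. Without lncRNA transcripts 355 genes passed (207 higher, 148 lower), and with quality weights 2078 genes (966 higher, 1112 lower) and 36 lncRNAs (9 higher, 27 lower); the weight of control replicate 1 was 0.131, against 1.10 to 1.998 in the others. On log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) with no filter, 95, 74 and 25 genes passed (68, 53 and 18 higher; 27, 21 and 7 lower) and 33, 15 and 21 lncRNAs. Calls on TPM were 71.6% to 72.0% higher, against 60%, and with DESeq2 47.9%. RLE, upper-quartile scaling, no filter and robust dispersion gave 192 to 207 genes and 0 lncRNAs. With 1 library left out, genes ranged from 0 to 1825 (0 to 965 higher, 0 to 860 lower), lncRNAs from 0 to 45, lists from 7 to 18 and terms from 0 to 28. The 1825 genes (without control replicate 1) included the 200; genes numbered 0 without control replicate 2, 10 without control replicate 3, and 1, 0 and 0 without heat replicates 1, 2 and 3. Of 37 named genes past the threshold, 37 kept their sign in every fit. Control and heat libraries did not overlap for these genes, so this adds little. With an estimated correlation or fry, 0 lists passed (18 with fry in either direction).

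The replicate block left 0 genes (0 higher, 0 lower; 2951 at an unadjusted p under 0.05), and 10 lists and 4 terms passed, with fatty acid oxidation (0.0499) and digestive hydrolases (0.0315) among the lists. Deviations from the group mean of same-numbered libraries correlated at -0.01, -0.01 and 0.04, and 1 of 3 controls matched its own number best. No pairing by number was seen, but so few libraries cannot exclude one. With the block, log2 fold changes turned to 0.135 for hsf1, 0.0127 for LOC119918460, 0.0908 for LOC119898530 and 0.055 for LOC119893780.

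Signs of named genes that had not passed turned as follows. With quality weights, log2 fold changes were 0.51 for LOC119918460, 0.22 for LOC119918458, 0.76 for LOC119898530 and 0.75 for LOC119893780. On TPM (pseudocount 1, then 0.1) they were 0.189 and 0.199 for hsf1, 0.0257 and 0.0264 for LOC119918460, 0.0611 and 0.0614 for LOC119898530, and 0.0042 and 0.0045 for LOC119893780; il1b was at 0.0064 with 0.1. With 1 library left out they ranged from -0.0908 to 1.505 for LOC119895682, -0.43 to 0.34 for hsf1, -0.24 to 0.17 for il1b, -0.56 to 0.61 for LOC119918460, -0.70 to 0.44 for LOC119918458, -0.43 to 0.22 for tjp1b, -0.79 to 0.83 for LOC119898530 and -0.94 to 0.85 for LOC119893780.

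Lists whose direction turned had not passed with all libraries. With quality weights, adjusted p was 0.391 for splicing factors, 0.330 for oxidative stress, 0.519 for enterocytes, 0.000182 for ribosomal proteins, 0.000484 for the respiratory chain, 0.0758 for the proteasome, 0.308 for goblet cells, 0.810 for macrophages and 0.839 for pancreas. With symbols only it was 0.777 for tight junctions, 0.613 for B cells, 0.297 for goblet cells, 0.855 for macrophages and 0.830 for pancreas. With no filter it was 0.916 for liver and 0.901 for macrophages. For pancreas it was 0.935 with fry, 0.987 with RLE, 0.970 with upper quartiles and 0.975 without lncRNAs. With 1 library left out, adjusted p ranged from 0.0136 to 0.291 for splicing factors, 0.0133 to 0.498 for oxidative stress, 0.0466 to 0.621 for enterocytes, 4.0e-07 to 0.562 for ribosomal proteins, 0.221 to 0.811 for tight junctions, 0.00557 to 0.856 for T cells, 1.0e-07 to 0.699 for the respiratory chain, 0.329 to 0.977 for liver, 0.00458 to 0.802 for the proteasome, 0.0958 to 0.815 for MHC class II, 0.592 to 0.915 for pathogen sensing, 0.405 to 0.905 for B cells, 0.221 to 0.992 for goblet cells, 0.621 to 0.933 for macrophages and 0.00988 to 0.852 for pancreas. Without control replicate 1, ribosomal proteins, the respiratory chain and the proteasome passed as higher. Ribosomal proteins and the respiratory chain passed as lower without control replicate 2 (adjusted p = 0.00059 and 0.0206) and without control replicate 3 (0.0216 and 0.000264), as did the proteasome without control replicate 3 (0.00988). MHC class I passed as lower with the block (0.0265) and without lncRNAs (0.0433). The neighbours of called lncRNAs gave no value with all libraries, since 0 lncRNAs passed. In simulation at this replication 0% of genes changed 2-fold were recovered and 34% at 4-fold.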

Other observations

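The tests of epithelium against muscle in control replicate 1, of the clock folds without it and of the splits with an estimated correlation were chosen only after the result was seen, and the other tests of that library and the lncRNA neighbour test without it were chosen after its difference was known but before their own results. Without control replicate 1, 94 genes of cytoplasmic ribosomal proteins had a median log2 fold change of 0.44 (camera adjusted p = 4.0e-07), 107 respiratory chain genes 0.47 (1.0e-07) and 50 proteasome genes 0.33 (0.00458). In all libraries these lists had medians of -0.57, -0.59 and -0.36 and did not pass. Without control replicate 2 the ribosomal and respiratory lists passed as lower (0.00059 and 0.0206), and without control replicate 3 so did each of the 3 (0.0216, 0.000264 and 0.00988), so their direction depended on which control was left out. The assembled transcript MSTRG.16832.3 (NW_024040928.1, 14670002 to 14672112), chosen after its values were seen, had the smallest p of the lncRNAs (log2 fold change 6.17, SE 0.82, edgeR adjusted p = 0.111). It lies on the strand opposite the c-Fos-like gene LOC119909126, and without a stated strand setting the reads of both cannot be separated.

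Clock genes formed a pattern in 2 arms. The arntl, clock and npas2 genes had a log2 fold change above 0 in 4 of 4 cases (median 1.41, lowest 0.22), of which 1 passed, while 14 of 15 per, cry, nr1d, dbp, tef and ciart genes lay below 0 (median -1.78), of which 8 passed. This opposition is what pools taken at different clock times would show, and a shift of clock phase by heat itself could show it too; the labels give 9 h for both groups, which speaks against different sampling times if both were started together, but no clock times are given, so neither was checked directly. The odd composition of control replicate 1 is argued against by the folds: the medians of the arms lay 3.11 log2 units apart without it, against 3.19 in all libraries and 3.09 to 3.39 with 1 of the other libraries left out. That 9 of the 9 clock genes that passed with it still passed without it decides nothing, since each of the 200 genes did.

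Control replicate 1 stood apart, at a mean correlation of 0.864 with the other controls. With nuclear protein-coding genes alone it was 0.887 against 0.952 between the others, which argues against structural and mitochondrial RNA as the source. After thinning the controls to 12.3 M counts it was 0.860 against 0.934, which argues against depth. A library from polyadenylated RNA alone would lack histone mRNAs, but 65 histone genes lay 1.16 log2 units (median, relative to all genes) above the other controls. The H1-like genes among them lay lower, at -0.62 to 0.71 (not relative to all genes). Control replicate 1 also had the lowest rRNA share (0.134%) and the highest protein-coding share (95.8%) of all libraries. The histone median argues against such a library, but these other values leave it open. More epithelium and less muscle wall stays open only in part. Enterocyte markers exceeded smooth muscle markers by 0.743 log2 units. Yet smooth muscle markers were themselves 0.34 higher than in the other controls, against 0.09 for all genes, so a lower muscle share was not seen. Enterocyte markers lay 1.09 above the other controls, less than ribosomal proteins (1.96) or the respiratory chain (2.03). Those 2 lists mark no other cell type, so this does not decide whether epithelium was enriched. The other cell-type lists went both ways, from -0.84 for skeletal muscle to 0.98 for T cells. The design gives no biological grouping for this library, and no explanation from the biology of the fish was tested.

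Smooth muscle markers were lower at 34 °C as a list at the preset correlation, with 4 of 18 members past the threshold. With an estimated correlation the list did not pass (camera adjusted p = 0.934). Without control replicate 1 their median relative to all genes was -0.85, against -0.91 with it, so that library does not account for the pattern. A smaller share of muscle wall in the heat pools would lower the abundant markers alike; 13 of 14 did lie below the median gene, with an SD of 0.593 log2 units between them, and tissue share and regulation cannot be told apart from these values.

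Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 200 genes and the highest other 0, and 1 split, the real one, gave as many. For lists the real split gave 7 and the highest other 15, and 10 splits, the real one included, gave as many. For lncRNAs the real split gave 0 and the highest other 5, and for terms 0 and 74; with a real count of 0, 10 of 10 splits give as many by construction, which is no test. Each of the 9 other splits gave 10 to 15 lists and 16 to 74 terms, and with an estimated correlation each of the 10 splits gave 0 of both. The list calls at the preset correlation therefore do not set the temperature groups apart from other groupings. Whether a structure of the samples or the preset correlation gave them was not told apart. With control replicate 1 left out, 22 of 39 called lncRNAs with a gene within 100 kb (56.4%) shared its sign, against 322 of 631 lncRNAs (51.0%) whose own p was over 0.5 (two-sided permutation test, p = 0.619); within 10 kb it was 20 of 33 (p = 0.372). In 23 of the 39 pairs the lncRNA and the gene overlapped, so most were not separate neighbours and may share reads. A shared direction in these pairs was not detected.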
